A study of Mus musculus with 13 samples.

How the data were processed

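RNA sequencing had been run on 13 libraries of total RNA from mouse cells, and the deposited table gave 1 RPKM column per library (reads per kilobase of gene, scaled to the reads of the library, per the file headers). TopHat 1.3.0 and the mm9 genome are named in the submitters' processing notes. The counting tool, the annotation, the gene lengths, strand handling and filters are not given in the sources used here. The table held 15184 rows. The 8 rows that shared 1 identifier (Ptprf) were left out, which left 15176 genes, identified by the symbols in the table. No column was unused, and 0 pairs of columns were identical.

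The values were checked against gene lengths from the GRCm38 annotation, used for lengths and not for coordinates, for the 13440 genes (88.6%) found in it. In 10 libraries RPKM multiplied by the span of the gene, introns included, gave whole multiples of 1 step per library (64.8 to 73% of low values at a tolerance of 0.05 steps). Summed over genes, these products gave 0.613 to 0.804 assigned reads per sequenced read. In the other 3 libraries (CiPSC lines 6 and 11 and ESC replicate 4) such sums were 2.618 to 2.664, and sums with exonic length were 0.322 to 0.323. The former are too high if each read was assigned at most once, which was assumed. The 10 libraries were taken to hold reads per kilobase of gene span and the 3 libraries reads per kilobase of exon. By the value standing for unmeasured genes the 10 split again. MEF replicates 1 and 2, both GFP-negative libraries, the clusters and ESC replicates 1 and 2 held exact 0 (first set). MEF replicate 3, the colonies and ESC replicate 3 held 0.001 in its place (second set). The 3 exonic libraries formed the third set.

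Read depth was estimated from the steps as 8.81 to 17.68 M reads per library in the 10 gene-span libraries and could not be estimated in the third set. Estimated reads per gene, their exact 95% Poisson bounds and floors of 3 reads follow from this. Bounds and floors cover counting error only.

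Values were analysed as log2(RPKM + 1), with no further scaling between libraries. Genes at 1 RPKM or more in at least 2 libraries were tested (10647). R 4.3.3 and limma 3.58.1 were used: a linear model over all 13 libraries with 1 coefficient per group, a trend in the prior variance, and Benjamini-Hochberg adjustment per comparison. A term for the length scale was added after the values had shown 2 scales. The design fixed earlier had no such term, and the fit without it was kept as an alternative. With the term, ESC against MEF and GFP-negative against MEF rested on gene-span libraries, and CiPSC against ESC rested on both CiPSC lines against ESC replicate 4 with the spread pooled over all groups. CiPSC against MEF was the sum of CiPSC against ESC and ESC against MEF, since MEF had no exonic library. The fit had 6 residual degrees of freedom and a prior of 2.58. Genes with adjusted p under 0.05 and an absolute log2 change of 1 or more were called changed. Errors of log2 changes are standard errors (SE), and errors of RPKM are standard deviations (SD). A log2 change of RPKM + 1 depends on the pseudocount where a group lay near 0 and bounds no fold there.

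The libraries were grouped by their labels. The comparisons, the test, the thresholds, 31 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 10 called genes in each direction with the largest change, among genes whose group ranges did not overlap and whose mean in the higher group was 10 RPKM or more. It added up to 4 members per list with the smallest p, and always Pou5f1, Sox2, Nanog, Sall4, Gata4, Gata6, Sox17, Cdh1, Col1a1 and Thy1, of which Sox17 was not analysed here. For the single libraries it took the 10 largest rises and falls against the GFP-negative mean (clusters) or the clusters (colonies), at 10 RPKM or more in the higher. One gene that this rule took is not reported here. The lists covered pluripotency, primed epiblast, two-cell-like state, germline, fibroblast, EMT transcription factors and mesenchymal adhesion, epithelial, extraembryonic endoderm, trophoblast, mesendoderm, neural, endothelial, muscle, keratinocyte, macrophage and blood, Hox, imprinted and sex-linked genes, proliferation, senescence and p53 targets, polycomb, DNA methylation and TET, cAMP response, Wnt target, TGF-beta target, interferon, glycolysis, ribosomal protein, and heat shock and immediate early genes. The lists of adipocyte genes and mitochondrial transcripts had too few measured members and were not tested. Of 452 genes on the lists, 379 were in the table. Lists were tested with limma's camera (preset correlation 0.01) against all other genes, and again with an estimated correlation. They were also tested with fry, which asks another question: whether the list changed at all, without regard to other genes.

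The clusters and the colonies had 1 library each and were compared without a test. List medians there are given with their percentile among 10000 random lists of the same size matched on expression. A position was computed per gene called in ESC against MEF, as the share of the log2 distance from the MEF mean (position 0) to the gene-span ESC mean (position 1). The model was tested on simulated data with 200 changed genes, and recovered, at log2 changes of 1.5 and 3, 63% and 95% for ESC against MEF, 14% and 70% for CiPSC against MEF, 35% and 78% for CiPSC against ESC, and 50% and 96% for GFP-negative against MEF.

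Alternatives were a pseudocount of 0.1, quantile normalization, median-ratio scaling, no filter, a filter at 5 RPKM, a fit to only the 2 groups compared, a replicate block, each library left out in turn, only the libraries with numbered labels, and only ESC replicates 3 and 4. Added after the data had been seen were fits without the length-scale term, with a term for the library set, on exonic libraries alone, on reads per gene without lengths, and on values with lengths divided out. Equal replicate numbers across groups did not mark pairs: correlations across genes of the residuals of equally numbered libraries were −0.042, −0.067 and 0.083. The block fit therefore stands as an alternative only. Nothing in the sources says whether the replicates were separate cultures, so the p-values measure only the spread between these libraries.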

Results

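RNA was sequenced in 13 libraries of 6 groups that followed mouse fibroblasts through reprogramming with small molecules. The groups were mouse embryonic fibroblasts (MEF, n = 3) and Oct4-GFP-negative cells picked from cultures treated with the mix coded VC6TF (n = 2). Oct4-GFP-positive clusters and Oct4-GFP-positive colonies, both labelled VC6TF plus Z, had 1 library each. Embryonic stem cells of the R1 line (ESC, n = 4) and chemically induced pluripotent stem cell lines 6 and 11 (CiPSC, n = 2) completed the set. Oct4 is the protein of Pou5f1. Values were RPKM. In 10 libraries they were per kilobase of gene span at an estimated depth of 8.81 to 17.68 M reads. In CiPSC lines 6 and 11 and ESC replicate 4 they were per kilobase of exon, at unknown depth, and RPKM of these 3 libraries are given apart from the others. ESC values are means of replicates 1, 2 and 3 unless replicate 4 is named.

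ESC were compared with MEF to describe the end point and the start of the process. The core pluripotency factors separated them: Pou5f1 was 111 ± 35.5 RPKM in ESC and 0.0512 ± 0.0887 in MEF (SD, n = 3 each), Nanog 53.2 ± 1.98 and 0.050 ± 0.00802, and Sox2 96.3 ± 8.04 and 1.07 ± 0.937. Sall4, a zinc-finger factor of the same network, was 14.5 ± 0.927 and 0.00353 ± 0.00612. The largest rise was that of Dppa5a, an RNA-binding protein of pluripotent cells, with 643 ± 78.9 in ESC and 0.277 ± 0.480 in MEF. Their log2 changes were 6.70 ± 0.28 for Pou5f1, 5.69 ± 0.19 for Nanog, 5.65 ± 0.35 for Sox2, 3.95 ± 0.17 for Sall4 and 9.03 ± 0.31 for Dppa5a (SE, limma adjusted p = 2.28e-06 to 2.45e-05). Of the fibroblast list, the collagen chain Col1a1 was 11.1 ± 5.43 RPKM in ESC and 818 ± 872 in MEF, and the surface protein Thy1 2.0 ± 0.654 and 136 ± 69.1. The largest fall was that of the imprinted noncoding RNA H19, from 2114 ± 1330 in MEF to 3.84 ± 4.78 in ESC (log2 −9.06 ± 0.69, limma adjusted p = 6.73e-05). The ranges of ESC and MEF did not overlap for Pou5f1, Nanog, Sox2, Sall4, Col1a1 and Thy1, which were named whatever their values. Chance gives this for 10% of genes at 3 against 3.

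Of 29 measured pluripotency genes 24 rose in ESC and none fell (25 adjusted over the list alone; median log2 change 3.15, camera adjusted p = 8.25e-20, adjusted p = 0.00201 with an estimated correlation). The other large rises among named genes were Utf1 (6.23 ± 0.40), the Nodal co-receptor Tdgf1 (5.84 ± 0.20), Trh (5.65 ± 0.64), L1td1 (5.60 ± 0.34), the growth factor Fgf4 (5.42 ± 0.57) and the Nodal antagonist Lefty2 (5.24 ± 0.34). Among 8 primed epiblast genes 7 rose (7 adjusted over the list alone; median 3.01, camera adjusted p = 2.15e-07, adjusted p = 0.063 with an estimated correlation). Of these the signal Nodal was at 3.33 ± 0.17, its antagonist Lefty1 at 4.75 ± 0.26 and the de novo DNA methyltransferase Dnmt3b at 3.09 ± 0.18. Of 7 DNA methylation and TET genes 5 rose (5 adjusted over the list alone; median 1.95, camera adjusted p = 6.35e-05, adjusted p = 0.0494 with an estimated correlation). They included Tet1 (3.01 ± 0.20) and Dnmt3l (2.38 ± 0.19). Two-cell-like genes rose in 4 of 5 (4 adjusted over the list alone; median 1.93, camera adjusted p = 0.00242, adjusted p = 0.213 with an estimated correlation). Germline genes rose in 2 of 10 (2 adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.461 with an estimated correlation). Epithelial genes rose in 6 of 17 (6 adjusted over the list alone; median 0.69, camera adjusted p = 0.000417, adjusted p = 0.367 with an estimated correlation). The adhesion molecules Cdh1 (2.78 ± 0.18) and Epcam (2.81 ± 0.18) were among them. Proliferation genes rose in 9 of 20 (12 adjusted over the list alone; median 1.31, camera adjusted p = 3.19e-05, adjusted p = 0.116 with an estimated correlation). Glycolysis genes rose in 7 of 15 (7 adjusted over the list alone; median 0.99, camera adjusted p = 0.000878, adjusted p = 0.209 with an estimated correlation). Ribosomal protein genes rose in 4 of 20 (3 adjusted over the list alone; median 0.79, camera adjusted p = 0.00925, adjusted p = 0.416 with an estimated correlation). Of 15 polycomb genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.88, camera adjusted p = 0.0395, adjusted p = 0.2 with an estimated correlation). Phc1 stood at 3.04 ± 0.30 and Cbx8 at −1.06 ± 0.17.

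Fibroblast genes fell in 18 of 19 (18 adjusted over the list alone; median −4.10, camera adjusted p = 2.31e-21, adjusted p = 0.00392 with an estimated correlation). The matrix protein Postn was at −4.80 ± 0.27, the collagen chain Col6a1 at −5.49 ± 0.40 and the transcription factor Twist1 at −4.08 ± 0.32. EMT transcription factors and mesenchymal adhesion genes fell in 6 of 9 (6 adjusted over the list alone; median −2.26, camera adjusted p = 7.41e-09, adjusted p = 0.00712 with an estimated correlation). Among them were the repressor Snai2 (−3.38 ± 0.33) and the cadherin Cdh11 (−2.27 ± 0.17). TGF-beta target genes fell in 10 of 15 (11 adjusted over the list alone; median −2.91, camera adjusted p = 7.41e-09, adjusted p = 0.0494 with an estimated correlation). All 8 interferon genes fell (8 adjusted over the list alone; median −2.55, camera adjusted p = 7.43e-08, adjusted p = 0.0494 with an estimated correlation). Hox genes fell in 8 of 12 (8 adjusted over the list alone; median −1.30, camera adjusted p = 8.65e-10, adjusted p = 0.0494 with an estimated correlation). Imprinted genes fell in 9 of 18 and rose in 2 (9 and 2 adjusted over the list alone; median −1.0, camera adjusted p = 0.00211, adjusted p = 0.318 with an estimated correlation). The growth factor Igf2 was at −7.36 ± 0.52 and Dlk1 at −6.57 ± 0.67. Extraembryonic endoderm genes fell in 5 of 12 (6 adjusted over the list alone; median −0.83, camera adjusted p = 0.00145, adjusted p = 0.213 with an estimated correlation). They included the basement membrane collagens Col4a1 (−2.96 ± 0.28) and Col4a2 (−2.52 ± 0.24), which fibroblasts also make. Gata4 and Gata6, endoderm transcription factors, had log2 changes of 0.04 ± 0.07 and −0.58 ± 0.21 (limma adjusted p = 0.737 and 0.0736). Both lay under 1 RPKM in the gene-span libraries of both groups, where a log2 change of 1 in RPKM + 1 could not be reached. Gata6 had about 3 to 10 reads in ESC and 98 to 301 in MEF, and was called lower with a pseudocount of 0.1. cAMP response genes fell in 2 of 10 (2 adjusted over the list alone; median −1.15, camera adjusted p = 0.0013, adjusted p = 0.0494 with an estimated correlation). Of 14 heat shock and immediate early genes 6 fell and 2 rose (6 and 2 adjusted over the list alone; median −0.84, camera adjusted p = 0.00145, adjusted p = 0.0542 with an estimated correlation). Fos, on both lists, was at −4.81 ± 0.39. Macrophage and blood genes, a check on other cells in the MEF cultures, fell in 2 of 5 (2 adjusted over the list alone; camera adjusted p = 0.015, adjusted p = 0.416 with an estimated correlation). The lysozyme gene Lyz2 was at −5.05 ± 0.57. MEF replicate 3 stood apart here, with 97.2 RPKM of Lyz2 beside 15 and 22.6 in replicates 1 and 2, and 14 of Laptm5 (named after its values were seen) beside 0.0586 and 0.164. Camera called no shift for the lists neural (median 0.87), mesendoderm (−0.02), trophoblast (0.17), sex-linked (0.13), senescence and p53 targets (0.50), Wnt target (0.25), endothelial (−0.10), muscle (0.19) and keratinocyte (0.59), with adjusted p = 0.441 to 0.933. The senescence and mesendoderm lists had a median and a mean of opposite sign (means −0.10 and 0.26), and the neural list had a positive median and a negative camera direction.

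In all, 1695 of 10647 genes changed between ESC and MEF (15.9%), 846 higher and 849 lower in ESC. All 24 named genes that were called, by size or always listed, kept their call under every alternative run. MEF and ESC also differed in culture, since ESC were grown on MEF feeder layers.

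**Figure D1:**
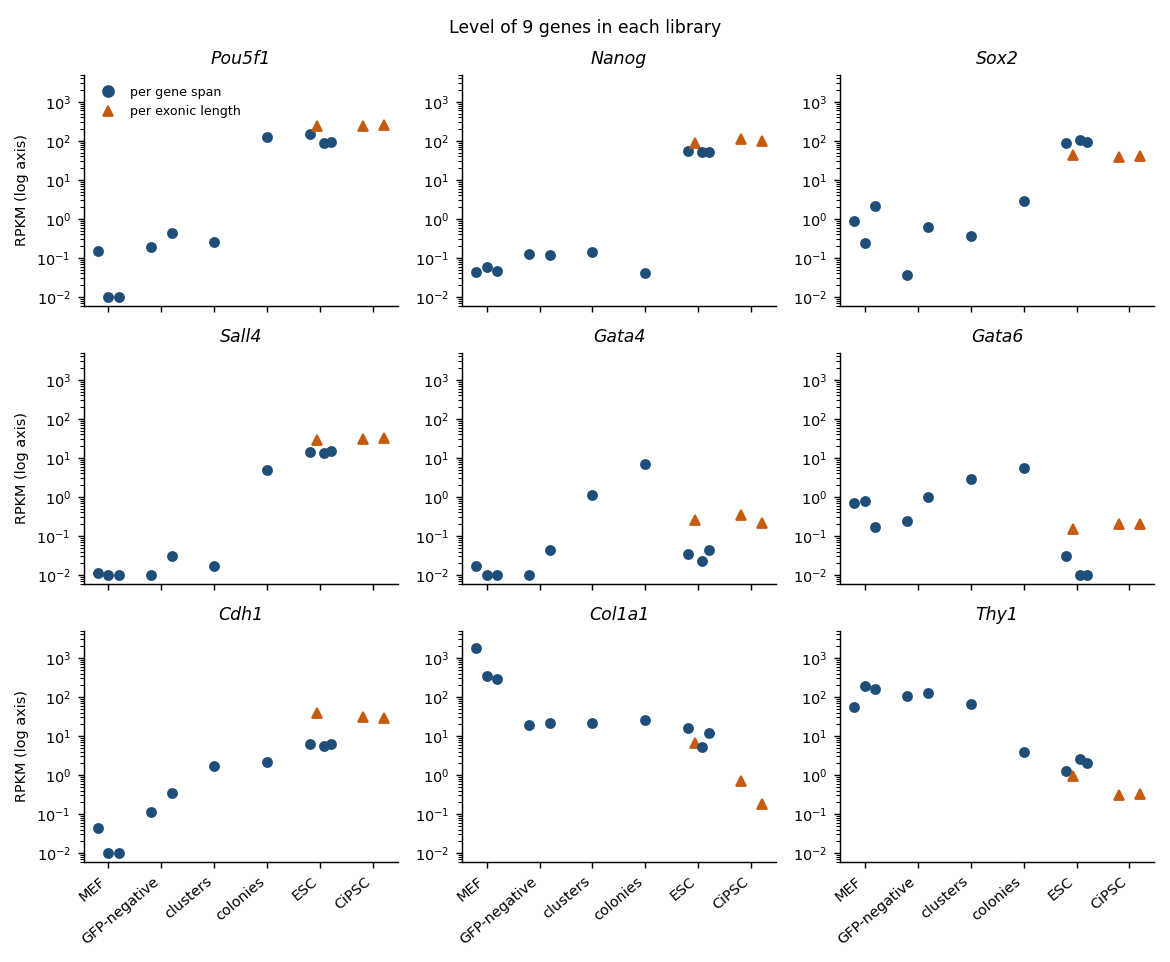
RPKM (log axis, values below 0.01 drawn at 0.01) of 9 genes in each library by group, with circles for values per kilobase of gene span and triangles for values per kilobase of exon. Pou5f1 in the colonies (124 RPKM) lies among the gene-span ESC values (86.1 to 152), while Nanog in the colonies (0.0420) lies with MEF.

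CiPSC were compared with MEF to ask how far the chemically induced lines had left the fibroblast state. On the exonic scale, for which MEF had no library, CiPSC held 252 ± 8.87 RPKM of Pou5f1, 105 ± 9.28 of Nanog, 38.9 ± 1.23 of Sox2 and 31.4 ± 1.18 of Sall4 (SD, n = 2). The estimated log2 changes from MEF were 6.78 ± 0.50 for Pou5f1, 5.94 ± 0.35 for Nanog, 5.49 ± 0.63 for Sox2 and 4.04 ± 0.32 for Sall4 (SE, limma adjusted p = 0.000158 to 0.00232). Col1a1 had an estimated change of −8.07 ± 1.25, the matrix protein gene Thbs1 of −8.52 ± 1.42, H19 of −8.80 ± 1.25 and Thy1 of −5.91 ± 0.80. Of the pluripotency list 18 of 29 rose (21 adjusted over the list alone; median 3.05, camera adjusted p = 2.39e-20, adjusted p = 0.00186 with an estimated correlation). All 19 fibroblast genes fell (19 adjusted over the list alone; median −5.03, camera adjusted p = 3.12e-27, adjusted p = 0.00198 with an estimated correlation). EMT genes fell in 6 of 9 (7 adjusted over the list alone; median −2.88, camera adjusted p = 5.83e-10, adjusted p = 0.00508 with an estimated correlation). TGF-beta target genes fell in 9 of 15 (10 adjusted over the list alone; median −3.27, camera adjusted p = 1.04e-10, adjusted p = 0.0373 with an estimated correlation). Interferon genes fell in 4 of 8 (7 adjusted over the list alone; median −2.24, camera adjusted p = 8.8e-08, adjusted p = 0.0449 with an estimated correlation). Hox genes fell in 5 of 12 (10 adjusted over the list alone; median −1.38, camera adjusted p = 5.26e-10, adjusted p = 0.0373 with an estimated correlation). Epithelial genes rose in 4 of 17 (6 adjusted over the list alone; median 1.54, camera adjusted p = 1.75e-05, adjusted p = 0.253 with an estimated correlation). Epcam was at 3.56 ± 0.32 and Cdh1 at 2.44 ± 0.32. Two-cell-like genes rose in 4 of 5 (4 adjusted over the list alone; median 4.03, camera adjusted p = 1.42e-05, adjusted p = 0.0942 with an estimated correlation). DNA methylation and TET genes rose in 3 of 7 (5 adjusted over the list alone; median 2.06, camera adjusted p = 2.47e-05, adjusted p = 0.0373 with an estimated correlation).

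In all, camera called 17 lists between CiPSC and MEF, of which 9 kept their call with an estimated correlation, and 15 were also called with fry, which tests against no change. Between CiPSC and MEF 557 genes changed (5.2% of those tested), 274 higher and 283 lower in CiPSC. This estimate passes through ESC, so genes it shares with ESC against MEF are shared by construction. The count was 173 without CiPSC line 11 and 181 without line 6 (Fgf4, Thbs1 and Col1a2 lost their call in 1 or both of these fits), and 5877 with no length-scale term, a fit that sets exonic against gene-span values.

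CiPSC and ESC were compared to ask in what the induced lines differed from stem cells derived from embryos. None of the core pluripotency factors was called, with the values side by side on the exonic scale: Pou5f1 was 252 ± 8.87 RPKM in CiPSC and 239 in ESC replicate 4, Nanog 105 ± 9.28 and 87.8, Sox2 38.9 ± 1.23 and 43.8, and Sall4 31.4 ± 1.18 and 29.4 (SD, n = 2 CiPSC and 1 ESC library). None of the 29 pluripotency genes changed (0 adjusted over the list alone; median −0.13, camera adjusted p = 0.377). Among genes of the transient two-cell-like state of stem cells, Gm4340 was 36.3 ± 7.01 and 2.09 RPKM (log2 3.58 ± 0.42, limma adjusted p = 0.0123). Zscan4d, of a family of telomere-associated factors, was 4.48 ± 0.667 and 0.507 (log2 1.86 ± 0.26, limma adjusted p = 0.0359). Of the 5 list members 2 rose (4 adjusted over the list alone; median 2.09, camera adjusted p = 1.31e-10, adjusted p = 0.098 with an estimated correlation). These genes belong to families of near-identical copies, and their values are uncertain. Ipp rose from 1.19 RPKM in ESC replicate 4 to 14.9 ± 0.503 in CiPSC (log2 2.85 ± 0.34, limma adjusted p = 0.0123).

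With lengths divided out, which sets all ESC libraries beside CiPSC, Gm4340 was 84.6 and 66.1 in the CiPSC lines, 4.57 in ESC replicate 4, and 14.7 to 25.4 in the other ESC libraries. Both CiPSC lines lay above all 4 ESC libraries in 4 of the 5 two-cell-like genes, and ESC replicate 4 was the lowest ESC library in 4 of them. In the pluripotency list both CiPSC lines lay above all 4 ESC libraries in 6 of 29 genes and below all 4 in 0. Against ESC replicate 4 alone both lay below in 17 and above in 8, and replicate 4 was the highest ESC library in 21. Dnmt3l was 120 and 162 in CiPSC and 58.0 to 71.6 in ESC. Ipp was 50.9 and 49.9 in CiPSC and 1.36 to 5.97 in the 4 ESC libraries. It was not particular to CiPSC, with 46.5 and 2.6 in GFP-negative replicates 1 and 2, 32.2 in the colonies and 1.37 in the clusters.

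None of the 19 fibroblast genes was called between CiPSC and ESC (0 adjusted over the list alone), while the list as a whole lay lower in CiPSC (median −0.55, camera adjusted p = 1.19e-08, adjusted p = 0.0927 with an estimated correlation). Col1a1 was 0.450 ± 0.377 RPKM in CiPSC and 6.58 in ESC replicate 4 (log2 −2.41 ± 1.04, limma adjusted p = 1). The smooth muscle actin gene Acta2 had a log2 change of −2.96 ± 0.83 (limma adjusted p = 0.419). With lengths divided out both CiPSC lines lay below all 4 ESC libraries in 17 of the 19 fibroblast genes. The same held for 6 of the 8 primed epiblast genes, of which none was called (1 higher and 1 lower adjusted over the list alone; median −0.37, camera adjusted p = 0.327, adjusted p = 0.766 with an estimated correlation). The TGF-beta target list, which holds Col1a1 and Acta2 too, had a median of −0.47 with no called member (1 lower adjusted over the list alone; camera adjusted p = 0.000148, adjusted p = 0.285 with an estimated correlation). The sex-linked list had a median of 0.59 over 3 genes with none called (0 adjusted over the list alone; camera adjusted p = 0.00279, adjusted p = 0.24 with an estimated correlation). With lengths divided out both CiPSC lines lay above ESC replicate 4 in 3 of these 3 genes and above all 4 ESC libraries in 0. Eif2s3y was 34.2 and 31.5 in CiPSC, 18.9 in ESC replicate 4, and 58.1 and 56.8 in ESC replicates 1 and 2. The epithelial list had a median of 0.38 with none called (1 higher adjusted over the list alone; camera adjusted p = 0.0101, adjusted p = 0.62 with an estimated correlation). With fry, which tests a list against no change, the 4 lists called by camera in this paragraph were not called: fry adjusted p = 0.134 for fibroblast, 0.344 for TGF-beta target, 0.172 for sex-linked and 0.751 for epithelial genes.

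Between CiPSC and ESC 17 genes changed (0.2% of those tested), 13 higher and 4 lower in CiPSC, and 507 had an unadjusted p under 0.05 by limma. The 4 lower genes, named after their values were seen, were Gm364, Ppp1r14d, Slc30a2 and Xlr3c. With lengths divided out both CiPSC lines lay above all ESC libraries in 10 of the 11 higher genes with known lengths, and ESC replicate 4 was below the other ESC libraries in 5 of the 11. They lay below all ESC libraries in 1 of the 4 lower genes. Gm364 was not that gene, with 2.66 and 3.56 in CiPSC and 1.08 to 25.2 in ESC. The balance of directions did not hold, with 3 higher and 15 lower in the fit with lengths divided out and 18 and 32 without a filter. The count rests on 1 ESC library and pooled spread: it was 10 without CiPSC line 6, 46 without ESC replicate 3 and 0 when only the 2 groups were fitted (628 at an unadjusted p under 0.05 by limma). Gm4340 and Ipp lost their calls under that fit, a pseudocount of 0.1, median-ratio scaling and lengths divided out, and without either CiPSC line. Ipp also lost it with quantile normalization, and Gm4340 without the length-scale term. The call of Zscan4d was not followed in each fit. It was lost at least with median-ratio scaling and with only the 2 groups, where 0 genes were called higher. ESC are of strain 129 and CiPSC of C57xICR per the labels, and strain and origin cannot be told apart here.

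**Figure D2:**
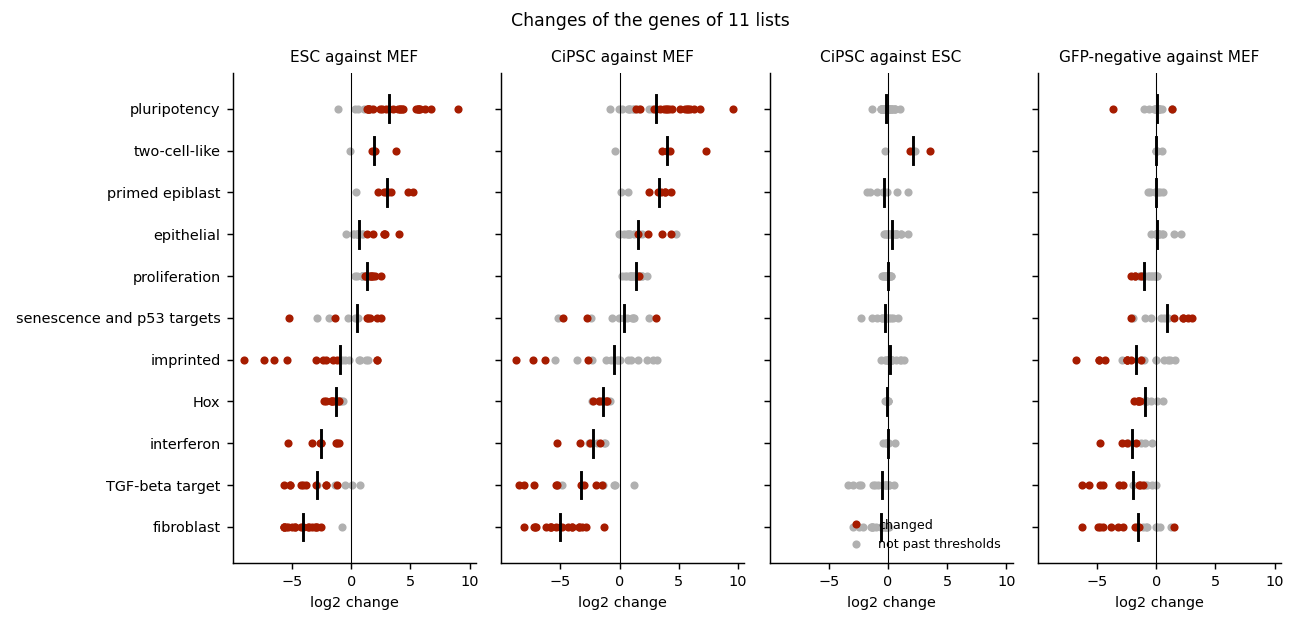
Log2 change (RPKM + 1) of each member of 11 gene lists in 4 comparisons, with changed genes in red, genes not past the thresholds in grey and a black bar at each median. The fibroblast medians are −4.10 in ESC and −5.03 in CiPSC against MEF, and the pluripotency median in GFP-negative cells against MEF is 0.04.

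GFP-negative cells were compared with MEF to describe treated cells that had not turned on the reporter. None of the core pluripotency factors was called: Pou5f1 was 0.310 ± 0.169 RPKM (SD, n = 2) and 0.0512 ± 0.0887 in MEF (n = 3), Nanog 0.124 ± 0.00315 and 0.050 ± 0.00802, and Sall4 0.0194 ± 0.0144 and 0.00353 ± 0.00612 (limma adjusted p = 0.568, 0.822 and 0.969). Sox2 was at 0.037 and 0.631 RPKM, beside 0.889, 0.24 and 2.087 in MEF. Pou5f1, Nanog and Sall4 lay under 1 RPKM in both groups, where a log2 change of 1 in RPKM + 1 could not be reached. Small changes there are not excluded. Differences at such levels ran mostly upward in the pluripotency list, on few reads. Pou5f1 and Nanog lay above all MEF libraries in both GFP-negative libraries. Zfp42 was 0.083 and 0.113 RPKM, beside 0 to 0.005 in MEF, and Dppa4 0.171 and 0.202, beside 0 to 0.011. Esrrb was 0.041 and 0.039 RPKM, beside 0.001 to 0.003 in MEF. Fbxo15 went the other way, at 0.027 and 0.063, beside 0.097 to 0.227, and Lin28a and Gdf3 overlapped MEF. Zfp42, Dppa4, Esrrb, Fbxo15, Lin28a and Gdf3 were named here after their values were seen. The largest rise was that of Ptgs2, the inducible cyclooxygenase, from 1.06 ± 0.709 to 99.6 ± 14.8 RPKM (log2 5.66 ± 0.35, limma adjusted p = 4.59e-05). The secreted glycoprotein Stc1 rose from 0.711 ± 0.245 to 57.7 ± 1.62 (log2 5.11 ± 0.21, limma adjusted p = 6.79e-06). The matrix phosphoprotein Spp1 rose from 17.1 ± 8.65 to 422 ± 46.7, and the retinoic acid-binding protein Crabp1 from 3.62 ± 2.23 to 102 ± 3.99. Genes that fell included Tagln at −6.25 ± 0.63, Ctgf at −5.70 ± 1.09, Col1a1 at −4.75 ± 0.77 and Col1a2 at −4.94 ± 0.71. Thy1 was 117 ± 15.3 RPKM in GFP-negative cells and 136 ± 69.1 in MEF, with a log2 change of −0.05 ± 0.49 that was not called.

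Fibroblast genes fell in 10 of 19 and rose in 1, the transcription factor Twist2 at 1.48 ± 0.14 (12 and 2 adjusted over the list alone; median −1.52, camera adjusted p = 0.000206, adjusted p = 0.179 with an estimated correlation). TGF-beta target genes fell in 9 of 15 (10 adjusted over the list alone; median −1.93, camera adjusted p = 2.18e-06, adjusted p = 0.179 with an estimated correlation). Interferon genes fell in 4 of 8 (6 adjusted over the list alone; median −2.05, camera adjusted p = 3.46e-05, adjusted p = 0.182 with an estimated correlation). Hox genes fell in 5 of 12 (5 adjusted over the list alone; median −0.92, camera adjusted p = 4.56e-05, adjusted p = 0.182 with an estimated correlation). Imprinted genes fell in 9 of 18 (10 lower and 1 higher adjusted over the list alone; median −1.71, camera adjusted p = 0.00415, adjusted p = 0.41 with an estimated correlation). Dlk1 was at −6.79 ± 0.74, H19 at −4.80 ± 0.77 and the cell-cycle inhibitor Cdkn1c at −4.85 ± 1.0. Proliferation genes fell in 4 of 20 (5 adjusted over the list alone; median −1.03, camera adjusted p = 0.00753, adjusted p = 0.365 with an estimated correlation). The survivin gene Birc5 was at −2.15 ± 0.33 and Mki67 at −1.78 ± 0.47. Senescence and p53 target genes rose in 5 of 13 and fell in 1 (5 and 1 adjusted over the list alone; median 0.94, camera adjusted p = 0.00989, adjusted p = 0.179 with an estimated correlation). The cell-cycle inhibitors Cdkn1a (2.27 ± 0.35) and Cdkn2a (2.25 ± 0.41), Pmaip1 (3.01 ± 0.34), Ccng1 and Mdm2 rose, and Igfbp3 fell (Mdm2 and Igfbp3 were named after their values were seen). The keratinocyte list shifted upward with 1 of 5 members risen, Krt5 at 2.13 ± 0.42 (1 adjusted over the list alone; camera adjusted p = 0.02, adjusted p = 0.182 with an estimated correlation). Among the pluripotency list Tbx3 rose (1.33 ± 0.26) and Klf2 fell (−3.61 ± 0.39) (1 and 1 adjusted over the list alone; camera adjusted p = 0.255). Of 12 extraembryonic endoderm genes 3 rose (3 adjusted over the list alone; camera adjusted p = 0.105), one of them the endoderm transcription factor Foxa2 (2.09 ± 0.25). Gata4 and Gata6 had log2 changes of 0.02 ± 0.08 and 0.06 ± 0.23 that were not called. Gata4 stood at 0.043 RPKM or less and Gata6 at 1.023 or less in these libraries. At such levels a log2 change of 1 in RPKM + 1 was out of reach. Cdh1 had 0.28 ± 0.20, not called, and was called higher with a pseudocount of 0.1 (1.46).

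Between GFP-negative cells and MEF 811 genes changed (7.6% of those tested), 376 higher and 435 lower in GFP-negative cells. The count was 5 when only the 2 groups were fitted, where 16 of the 20 named genes called by size lost their call. It was 1499 without GFP-negative replicate 2, and 490 and 488 without CiPSC lines 6 and 11, which enter through the pooled spread. Tcp1 (3.98 ± 0.93) overlaps its neighbour Acat3 and differed among ESC libraries (57.7 to 595 RPKM), so its rise is uncertain.

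Of the 376 genes higher in GFP-negative cells 42 were also higher and 49 lower in ESC than in MEF, and of the 435 lower genes 211 were also lower and 24 higher in ESC. Independent lists of these sizes would share 29.9 higher and 34.7 lower genes. Both comparisons use the same 3 MEF libraries, which were not divided between them, so part of the excess may come from the shared libraries. In 100 simulations with no true change 0 genes were higher in both and 0 lower in both, which does not measure what shared libraries add to lists of this length. The log2 changes correlated across genes with r = 0.243, below the simulated mean of 0.446, and with a covariance of 0.202, above the simulated 0.067. Genes are not independent replicates.

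The GFP-positive clusters and colonies were compared with the other gene-span libraries to place them between MEF and ESC, without replicates and without a test. The clusters, though picked as GFP-positive, held Pou5f1 at 0.260 RPKM (about 11 reads, 95% interval 0.131 to 0.471), beside 0.191 and 0.429 RPKM in the GFP-negative libraries. Nanog was 0.141 RPKM (9 reads) and Sall4 0.0170 (3 reads). The endoderm factors Gata4 and Gata6 were at 1.14 RPKM (about 731 reads, 95% interval 1.06 to 1.23) and 2.90 RPKM (about 847 reads, 95% interval 2.71 to 3.10), where GFP-negative cells had 0.0010 and 0.0430 of Gata4 and 0.243 and 1.02 of Gata6. Foxa2 went the other way, at 0.0540 RPKM beside 2.08 and 5.25, and the extraembryonic endoderm list had a median of −0.05 against GFP-negative cells (percentile 47.5). Cdh1 was 1.71 RPKM, beside 0.116 and 0.353 in GFP-negative cells. Among the largest differences from the GFP-negative mean were higher values of Gjb5, a gap junction protein (37.64 against 0.52 RPKM), Gadd45b (31.41 against 0.48) and the transcription factor Klf2 (25.52 against 0.26). The MEF libraries held 0.05 to 0.37 RPKM of Gjb5, 3.51 to 23.22 of Gadd45b and 9.93 to 22.59 of Klf2. As lists, glycolysis genes lay higher than in GFP-negative cells (median 0.65, percentile 99.4) and fibroblast genes (−0.74, percentile 1.3) and senescence and p53 target genes (−1.02, percentile 0.4) lower. Lower too were keratinocyte genes (−1.24, percentile 0.1), heat shock and immediate early genes (−0.99, percentile 0.7) and cAMP response genes (−0.78, percentile 2.5). The Y-linked genes Eif2s3y, Uty and Ddx3y were named after their values were seen. Eif2s3y and Uty were at 0 RPKM in the clusters, where GFP-negative cells had 2.20 and 0.286 of Eif2s3y and 0.0315 and 0.00455 of Uty. Ddx3y was present in the clusters at 0.281 RPKM, beside 0.568 and 1.52. The colonies were low in these genes too, with 0.0435 RPKM of Eif2s3y, 0.00134 of Uty and 0.284 of Ddx3y. Against MEF the fibroblast median was −2.03.

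In the colonies Pou5f1 stood at 124 RPKM (about 5846 reads, 95% interval 120.4 to 127), which is 81.33% of ESC replicate 3, the ESC library of the same set. Nanog was 0.0420 RPKM (about 3 reads, 95% interval 0.0090 to 0.123), against 51.7 to 55.4 in the gene-span ESC libraries. Sox2 was at 2.80 RPKM (69 reads) and Sall4 4.85 (912 reads). Gata4 reached 6.82 RPKM (about 4947 reads, 95% interval 6.63 to 7.01) and Gata6 5.39 RPKM (about 1780 reads, 95% interval 5.14 to 5.65), the highest of the 10 gene-span libraries for both. Other genes of the extraembryonic endoderm list, chosen for naming after their values were seen, followed: Foxa2 21.6 RPKM, Foxq1 47.6, the laminin chains Lama1 41.3 and Lamb1 58.3, and Pth1r 39.4. Of 16 genes on that list 14 were higher than the MEF mean by a log2 difference of 1 or more (median 2.80, percentile 100), and 15 were higher than the ESC mean (median 3.55). Of 18 list genes in the table, these 16 reached 1 RPKM in any gene-span library, the colonies included. Genes high only in the colonies could thus enter, which can raise the counts. The endothelial list lay higher too, at 1.22 against MEF (percentile 99.9) and 1.90 against ESC (percentile 100). Two-cell-like genes lay higher than in MEF in 4 of 6 and lower in 1 (median 1.76, percentile 100), with a median of −0.40 against ESC (percentile 10). Germline genes lay higher than in MEF in 3 of 5 (median 1.03, percentile 99.2). Their median was 0.69 against ESC (percentile 96.8) and 0.05 against ESC replicate 3 alone. The macrophage and blood list was at 1.03 against ESC (percentile 99.1) and −0.47 against MEF (percentile 2.9), and at −2.47 against MEF replicate 3 alone, with 7 of 7 members lower. The pluripotency list lay between, 1.39 above MEF (percentile 100) and at −1.53 against ESC (percentile 0). Epithelial genes lay higher than in MEF in 12 of 15 (median 1.63) and fibroblast genes lower in 18 of 20 (median −3.82), while against ESC 5 of the 20 were higher and 2 lower by a log2 difference of 1 or more (median 0.02). Proliferation genes lay below ESC in 16 of 20 (median −1.54) and primed epiblast genes had a median of −2.73. Against the libraries of the same set, the list medians were 2.48 for extraembryonic endoderm and 1.33 for pluripotency against MEF replicate 3. Among the largest differences from the clusters were higher values of Dppa5a (512.97 against 0.30 RPKM), Pou5f1 and the phosphatase Dusp9 (82.02 against 0.19). Star, the steroidogenic acute regulatory protein, was lower (0.33 against 87.51), as were Ptgs2 and Stc1. The colonies and the clusters belong to different library sets, so set and cell state cannot be told apart in these differences. Rps21, in the same ranking, differed by set within ESC (127.02 RPKM in replicate 3, 8.02 and 3.79 in replicates 1 and 2). Dppa5a did not (686.69 beside 690.67 and 552.05).

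On the scale from MEF (0) to ESC (1), the 1695 genes changed between ESC and MEF had a median position of 0.09 in each GFP-negative library, 0.11 in the clusters (quartiles −0.25 to 0.75) and 0.36 in the colonies (0.02 to 0.80). Genes lower in ESC lay farther along than genes higher in ESC. Their medians were 0.43 and −0.03 in GFP-negative replicate 1 and 0.33 and 0 in replicate 2. They were 0.49 and −0.02 in the clusters, and 0.63 and 0.20 in the colonies. Across genes the clusters correlated with the GFP-negative libraries at r = 0.714 and 0.778, and these with each other at 0.803. The colonies correlated at 0.85 with MEF replicate 3 and 0.858 with ESC replicate 3, both of their set.

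**Figure D3:**
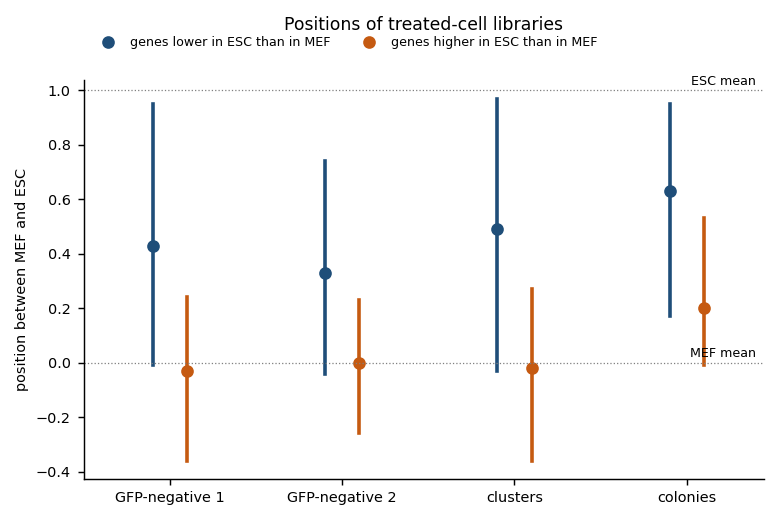
Median position between MEF (0) and ESC (1) of genes lower in ESC (blue) and higher in ESC (orange), with bars from the lower to the upper quartile, in the GFP-negative libraries, the clusters and the colonies. In the colonies the medians are 0.63 and 0.20.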

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

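The tests on lengths, on introns, on mixing in the colonies, on depth and on labels of the clusters were chosen only after the results had been seen.

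ESC replicate 4 stood apart from the other 3 ESC libraries. Its RPKM multiplied by gene span summed to 2.618 assigned reads per sequenced read, where the others gave 0.613 to 0.736 (Dixon ratio 0.939, over the 95% critical value). This was the only one of 5 measures tested to exceed the critical value, and chance exceeds it in about 1 of 20 groups. Gene-span values with more reads from introns are excluded if each read was assigned at most once, since the sum was 2.618. That was assumed, as the counting tool is not given. Another length definition remains: the log2 ratio of replicate 4 to replicate 3 rose with the log2 ratio of span to exonic length with a slope of 0.89, and a term for the length scale was used for this reason. No biological explanation was tested.

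In ESC against MEF, 3 libraries against 3 make only 10 splits, too few for a share under 0.05: the real split gave 1695 genes and the highest of the other splits 1.

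Fibroblast genes lay lower in CiPSC than in ESC, with a median log2 change of −0.55 over the list. RNA from the MEF feeder layers under both cell types, in larger amount in the ESC libraries, is one candidate explanation. The fibroblast list stood at 1.01 to 1.68% of the MEF level in the 4 ESC libraries and at 0.163% and 0.0618% in the CiPSC lines. The 50 most abundant MEF genes among those at a log2 change of −3 or lower in ESC against MEF were also taken. They stood at 1.23 to 2.41% in ESC and at 0.246% and 0.225% in CiPSC. That choice by itself made their shares in ESC low. Against feeders with the profile of the MEF libraries stand H19, at 0.0369 to 0.361% in ESC, and Igf2, at 0.037 to 0.841%, which lay below those shares in each ESC library. Feeder cultures with less H19 and Igf2, residual differentiation in the ESC cultures and the difference in strain remain open and were not tested.

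Pou5f1 was near the ESC level in the colonies and at the level of GFP-negative cells in the clusters, although both were picked by the same reporter. ESC-like cells mixed into the colonies are excluded as the source of Pou5f1. The other 14 pluripotency genes at 10 RPKM or more in ESC replicate 3 stood at a median of 4.84% of that library, where Pou5f1 stood at 81.33%. Nanog stood at 0.08% and Sox2 at 3.11%, though Nr0b1 stood at 51.52%, Dppa5a at 74.7% and Klf4 at 230.29%. List genes under 10 RPKM there were not counted and went both ways. Klf5 (12.9 against 4.04 RPKM), Tcl1 (8.61 against 3.19) and Tbx3 (6.59 against 5.65) lay above ESC replicate 3. Prdm14 (0.022 against 1.725) and Nr5a2 (0.003 against 0.423) lay far below it. Too few reads in the clusters library are excluded too, since the level of the colonies would have given 5166 reads and 11 were found. A wrong label on the clusters cannot be told apart from a real difference: they stood apart from both GFP-negative libraries at 184 genes, and each GFP-negative library from the other two at 139 and 90, while Gata4, with 731 reads against 1 and 32, and the Y-linked Eif2s3y, at 0 RPKM against 2.20 and 0.286 (0.0435 in the colonies; Ddx3y at 0.281 against 0.568 and 1.52, and 0.284 in the colonies), set the clusters apart from both but were chosen for this question after their values were seen and also differ between the GFP-negative libraries. A lag between reporter and transcript, few GFP-positive cells among those picked, and different stages of reprogramming remain open and were not tested.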

How the results depend on the processing

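The fits without the length-scale term, with the library set as a term, on exonic libraries alone, on reads per gene and with lengths divided out, and the positions within 1 library set, were chosen after the data had been seen.

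No called gene named by size or always listed changed direction under any alternative run. Genes named only through the lists were not followed there. No called list changed direction with an estimated correlation, fry, quantile normalization or the replicate block, the settings run for lists. Some lists that were not called changed direction. ESC against MEF gave 1695 genes, and 2590 with a pseudocount of 0.1, 2627 on reads per gene, 3479 with lengths divided out, and 1330 to 1859 with 1 library left out. CiPSC against MEF gave 557, and 354 with median-ratio scaling, 855 with the library set as a term, 3637 with lengths divided out, 5877 without the length-scale term, and 173 to 755 with 1 library left out (173 without CiPSC line 11, 181 without line 6). CiPSC against ESC gave 17, and 3 with a pseudocount of 0.1, 4 with quantile normalization, 2 with median-ratio scaling, 50 without a filter, 2 with a filter at 5 RPKM, 0 with only the 2 groups, 9 without the length-scale term, 33 with the library set as a term, 54 with only ESC replicates 3 and 4, 205 on exonic libraries alone, and 10 to 46 with 1 library left out. GFP-negative against MEF gave 811, and 1391 with a pseudocount of 0.1, 526 with a filter at 5 RPKM, where 5700 genes were tested, 5 with only the 2 groups, 353 with only the libraries that carry a number in the labels, 376 without the length-scale term, 1710 with lengths divided out, and 488 to 1499 with 1 library left out (488 and 490 without CiPSC lines 11 and 6, 593 and 1499 without GFP-negative replicates 1 and 2). Fits on part of the libraries and the filter at 5 RPKM used fewer libraries or genes by construction. For the other settings the cause was not tested.

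With lengths divided out 1450, 466, 3 and 633 of the genes called in the 4 comparisons, in the order above, were called in the same direction. The median log2 change of all genes moved from −0.128 to 0.016 (quantile) and −0.001 (median ratio) in GFP-negative against MEF, and from 0.174 to 0.048 (median ratio) in CiPSC against MEF. The higher genes were 46.4% of those changed in GFP-negative cells, 60.9% with median-ratio scaling and 33.6% with a pseudocount of 0.1, so the balance of directions there changes with the scaling and the pseudocount. In ESC against MEF the higher genes were 49.9%, 43.7% with quantile normalization, 40.2% with median-ratio scaling and 55.4% with a pseudocount of 0.1. In CiPSC against MEF they were 49.2%, 37.1% with quantile normalization and 36.2% with median-ratio scaling. In CiPSC against ESC they were 76.5%, 100% with a pseudocount of 0.1, 50% with quantile normalization or the block, 0% with median-ratio scaling, 36% without a filter, 46.3% on exonic libraries and 16.7% with lengths divided out. Median positions were 0.11 in the clusters (0.12 with a pseudocount of 0.1, 0.16 with quantile normalization, 0.1 within the library set) and 0.36 in the colonies (0.39, 0.35 and 0.38). For genes higher in ESC the colonies moved from 0.20 to 0.28 with a pseudocount of 0.1 and to 0.12 with quantile normalization. For genes lower in ESC they moved from 0.63 to 0.52 and 0.69. With quantile normalization the genes higher in ESC changed sign in the clusters (−0.02 to 0.04) and GFP-negative replicate 1 (−0.03 to 0.04).

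Replicate numbers did not mark pairs. With them as a replicate block the counts were 1986, 782, 20 and 948, and polycomb lost its call in ESC against MEF (block adjusted p = 0.116). With an estimated correlation 12 of 20, 8 of 17, 5 of 5 and 8 of 8 list calls were lost. With fry, a test against no change, 0 of 20, 2 of 17, 4 of 5 and 0 of 8 were not called. CiPSC comparisons could not be fitted without ESC replicate 4, nor CiPSC against MEF with only the 2 groups. A count model (DESeq2) was not run, since the table holds no counts. Where 1 library was left, it was assumed to vary like the other groups. Depth limits values near the floor of 3 reads, such as Nanog in the colonies.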

Other observations

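No test was run on these values, and all genes named here were chosen after their values were seen.

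Some genes stood higher in the clusters than in GFP-negative cells, without a shift of the endothelial, muscle and neural lists (medians 0.05, 0.06 and 0). The vascular receptor Kdr was at 24.6 RPKM, the intermediate filament Des at 24.9, the transcription factor Otx2 at 10.0 and the imprinted gene Peg10 at 63.5. GFP-negative cells had 0.469 and 0.250 RPKM of Kdr, 0.263 and 2.36 of Des, 0 and 0 of Otx2 (ESC 0.470 to 8.67) and 12.1 and 8.0 of Peg10. Cdkn1c, which fell in GFP-negative cells, was at 38.4 RPKM in the clusters and 3.24 and 2.22 in GFP-negative cells.

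The colonies held keratins of simple epithelia, with Krt8 at 30.8 RPKM and Krt18 at 34.1, the tight junction protein Cldn6 at 24.8, and the endothelial-list gene Egfl7 at 10.1. Klf4 stood at 230.29% of ESC replicate 3 and Dppa5a at 74.7%, while Fgf4 stood at 0%. Some genes differed between library sets within 1 group: Scand1 was 50.1 RPKM in MEF replicate 3 and 0.689 in replicate 1.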
